A study of Homo sapiens with 6 samples.

How the data were processed

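The samples were 6 RNA-seq libraries of THP-1-derived macrophages, 3 labelled normal and 3 labelled siCCR1, grouped by their titles. Per the labels' protocols, poly(A) RNA was selected, and libraries were made with dUTP marking of the second strand and sequenced as read pairs. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR without their roles. The only genome build in the submitters' processing notes is rn6, a rat assembly, while all 61806 row identifiers of the count tables are human Ensembl genes. The human build and annotation used by the authors are not given in the sources used here, nor is the strand setting of counting. Whether reads or fragments were counted is likewise not given in the sources used here.

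The authors deposited counts per gene, whole numbers that had not been scaled for depth, per the file headers and their values. The authors also deposited FPKM values (fragments per kilobase, scaled to depth) per gene name for 35510 rows, rounded to 2 decimals. Low counts had an excess at 4, with 1422 to 1574 genes at 4 counts per library against 816 to 919 at 3 and 481 to 557 at 5, so a count near that value says little. Symbols were matched by identifier to the supplied name table for 61757 genes and to the table or GENCODE release 29 for 61804 genes. Coordinates and 3' untranslated regions came from GENCODE release 29 (GRCh38) by gene identifier.

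Genes were filtered with edgeR's filterByExpr, which left 20534, and scaled by the trimmed mean of M-values. Normal and siCCR1 libraries were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3, robust fit, group as the only term), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Standard errors were obtained from the log2 fold change and the quasi-likelihood F. CPM values are scaled by the same factors. The biological coefficient of variation was 16%. Values of count-based and FPKM-based log2 fold changes had a Pearson r of 0.989 across 13492 genes, which are not independent replicates. The steps were tested on simulated data drawn for this comparison from the means, dispersions and library sizes of 20534 genes, in 5 simulations. A 1.5-fold change was recovered in 43% of genes, a 2-fold change in 62.4% and a 3-fold change in 78.8%, and 10.2% of the calls were genes that had not been changed, above the nominal share. A planted list was called in 5 of 5 simulations by camera and by fry, and 0 of 100 unchanged lists were called. Genes were drawn independently there, so these simulations could not show how the list tests behave when genes of a list vary together.

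Before the data were examined, 33 gene lists were fixed. They were pro-inflammatory (M1) and alternatively activated (M2) markers, CCR1 ligands, other chemokines, other chemokine receptors, NF-kB and TNF response, type I interferon response, inflammasome, MHC class II presentation, and phagocytosis, Fc and complement receptors. Metabolic and stress lists were cholesterol efflux, sterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, cell cycle, p53 and apoptosis, unfolded protein and integrated stress response, oxidative stress and metal response, immediate early genes, JAK-STAT, and lysosome and autophagy. Others were matrix and adhesion, pain mediators and growth factors, RNA interference machinery, double-stranded RNA and toll-like receptors, monocyte and progenitor markers, macrophage differentiation markers, urothelial, fibroblast and endothelial, and lymphocyte markers, mitochondrially encoded genes, ribosomal proteins and replication-dependent histones. Lists were tested with limma's camera on log2 CPM (prior count 2, inter-gene correlation 0.01) with adjustment over the 33 lists, and again with an estimated correlation and with fry.

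Genes named in the text followed a rule that was also fixed then. CCR1 came first, then the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, a mean of at least 5 CPM, groups that did not overlap and a symbol that is not a clone, antisense, pseudogene or mitochondrial name. Up to 4 members with the smallest p were added from each list described, together with CCR2, CCL3, CCL5, TNF, IL1B, IL6, IL10, MRC1, CD163, CD86 and CD80; a further gene of the rule is not reported here. Separation of 3 against 3 libraries occurs by chance in 10% of genes.

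Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other filters on low counts (none, or at least 1 CPM in 3 libraries), the replicate number as a block, each library left out in turn, and limma on log2(FPKM + 1) or log2(FPKM + 0.1) for genes with FPKM of at least 0.5 in 3 libraries, or without that filter. On the FPKM scale a fold change understates the change of low genes. A correction of each library for GC content and gene length, and the removal of genes with the leading 7-mers in the 3' untranslated region, were chosen after seeing the data. For the 7-mer search, all 16349 words of 7 bases present in at least 50 of 14732 genes with an annotated 3' untranslated region of at least 50 bases were scored. The score was the mean rank of the signed test statistic after removal of trends in length, GC content and expression, with 1000 permutations of the genes. In simulated data for this comparison over the same 14732 genes, a planted 7-mer came first and passed in 86% of 50 simulations at a shift of 0.15 SD and in 100% at 0.3 and 0.5 SD. Permutations treat genes as exchangeable, which co-regulated genes are not. This search used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.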

Results

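The transcriptomes of macrophage-like cells were measured by RNA sequencing of poly(A) RNA. The cells were THP-1, an established human monocytic leukaemia line, brought to the unpolarised M0 macrophage state. They were then exposed to conditioned medium of SV-HUC-1, an immortalised human urothelial line, which had been stimulated with tumour necrosis factor at 10 ng/mL for 24 hours. The labels gave a normal group of 3 libraries and a siCCR1 group of 3 libraries, although the series text speaks of duplicates. Small interfering RNA (siRNA) degrades the messenger RNA that it matches, and CCR1 is a receptor for inflammatory chemokines such as CCL3 and CCL5. The labels did not say whether normal cells received a control siRNA, so transfection was part of the contrast. They also did not say that replicates came from separate cultures, so p-values measured only the spread between these samples, which may be technical. Total counts ran from 50935979 to 58099285 per library, with 27392 to 28109 genes detected. Mitochondrial transcripts took 3.69 to 3.98% of the counts. All pairs of libraries within a group differed by far more than counting noise (chi-square per degree of freedom of 13.4 to 40.1).

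The targeted gene, CCR1 (ENSG00000163823), was examined first. CCR1 fell 2.70-fold, from 235 ± 27.8 CPM (counts scaled to library size; SD, n = 3) in normal libraries to 87.2 ± 6.65 CPM in siCCR1 libraries (SD, n = 3). The normal libraries held 266, 212 and 229 CPM of CCR1, and the siCCR1 libraries 85.2, 81.8 and 94.7 CPM. The log2 fold change was -1.43 (SE 0.09), with adjusted p = 0.000221 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. CCR1 lies on chromosome 3 from 46201709 to 46208396 on the minus strand in GENCODE release 29 (GRCh38), which may not be the build the authors used. The neighbouring receptor gene CCR2 gave a log2 fold change of -0.02 in edgeR's test, with adjusted p = 0.971. CCR3, whose annotated span overlaps CCR1 on the opposite strand, gave 0.53 (edgeR adjusted p = 0.299), and its reads could be mixed with those of CCR1 if strand was not used in counting.

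**Figure D1:**
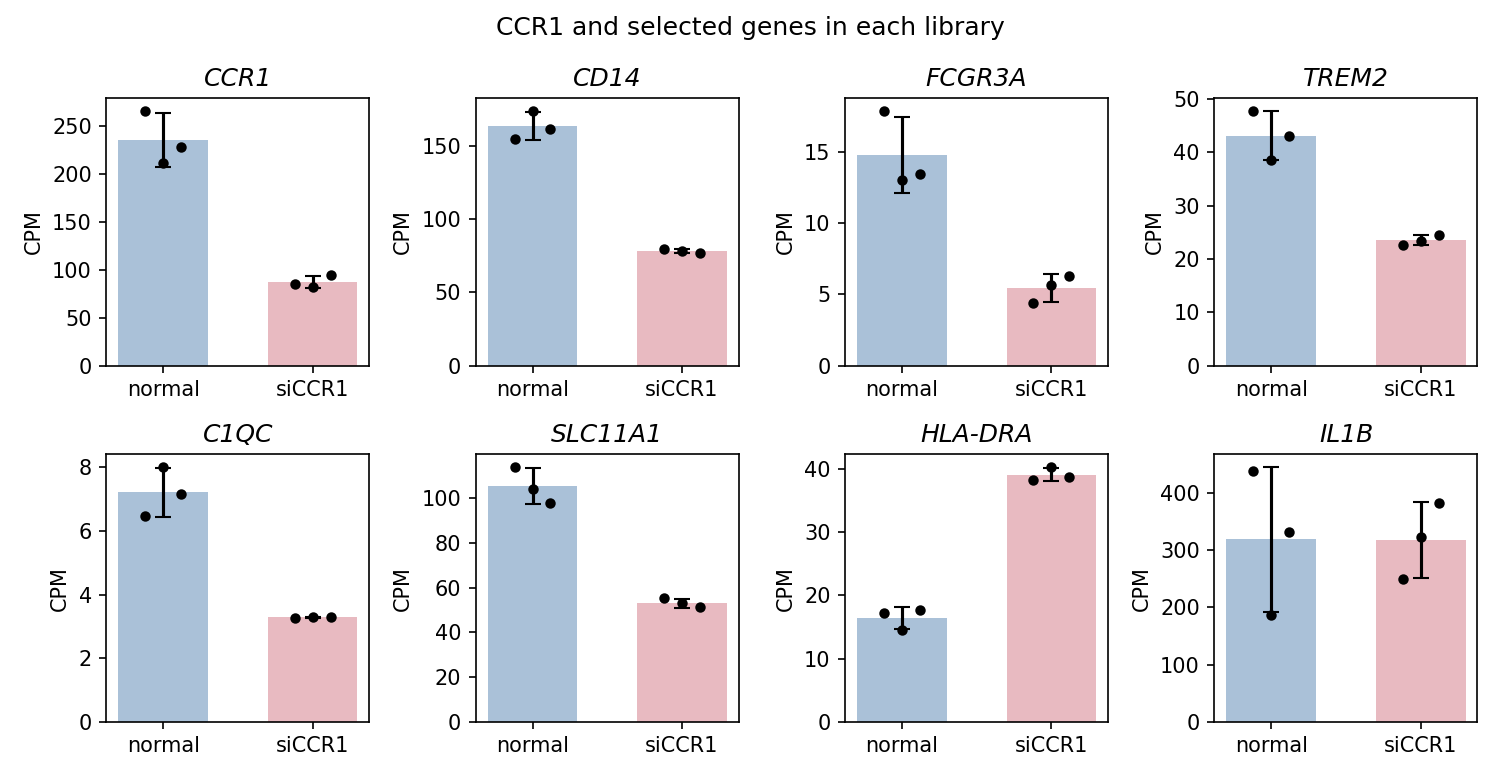
Counts scaled to library size (CPM, linear axes from 0) of CCR1 and 7 other genes named in the text. Bars give the mean of 3 libraries, error bars the SD and points the libraries. CCR1, CD14, FCGR3A, TREM2, C1QC and SLC11A1 were lower in each siCCR1 library than in each normal library and HLA-DRA was higher, while IL1B ranged from 186 to 438 CPM among the normal libraries.

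The contrast of siCCR1 with normal cells asks which genes of the macrophage state depend on CCR1, in a study of macrophage phenotype in interstitial cystitis. Receptors and opsonins of phagocytes were among the 116 genes that fell, with 9 members of the fixed phagocytosis list. The Fc receptor FCGR3A fell 2.71-fold, from 14.8 ± 2.68 to 5.45 ± 0.963 CPM (SD, n = 3 each). The lipopolysaccharide co-receptor CD14 fell 2.09-fold, from 164 ± 9.67 to 78.1 ± 1.38 CPM. On the higher side, HLA-DRA, the alpha chain of the HLA-DR antigen-presenting molecule, rose 2.37-fold, from 16.5 ± 1.74 to 39.1 ± 1.06 CPM.

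In edgeR's quasi-likelihood test, 215 of 20534 genes changed at adjusted p under 0.05, 99 higher and 116 lower in siCCR1 libraries. At least a 2-fold change was reached by 19 of the higher and 10 of the lower genes. The largest falls among genes that met the naming rule (a mean of at least 5 CPM), after FCGR3A and CCR1, were those of CREG1, a secreted lysosomal glycoprotein, and C1QC, a chain of complement C1q. Their log2 fold changes were -1.18 (SE 0.08, adjusted p = 0.000221) and -1.13 (SE 0.14, adjusted p = 0.0067). CD14 (-1.07), NKAIN1 (-0.99), the phagosomal metal transporter SLC11A1 (-0.99), C1QA (-0.94), the endoplasmic reticulum chaperone DNAJB11 (-0.93), CYB5R2 (-0.89) and the lipid-sensing receptor TREM2 (-0.87) followed. CREG1 and DNAJB11 carry the sequence AGGCTTAA in their longest annotated 3' untranslated regions, and that sequence was more frequent among the genes that fell than among all genes searched.

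The largest rises among genes that met the naming rule, which asks for a mean of at least 5 CPM, were those of RAB3C, a GTPase of secretory vesicles, with a log2 fold change of 1.53 (SE 0.24, adjusted p = 0.0286 by edgeR), and of RBM14-RBM4 (1.27). RBM14-RBM4 is a readthrough transcript that shares its reads with RBM14 and RBM4, so its value is uncertain. HLA-DRA (1.24), the interleukin-31 receptor chain IL31RA (1.11), SEC16B (1.10), the matrix glycoprotein thrombospondin-1 THBS1 (1.09), the heparan sulfate sulfatase SULF2 (1.02), the non-coding LINC00996 (1.01), the aldo-keto reductase AKR1C3 (0.95), which has close paralogs, and CLSTN2 (0.89) followed. The count of changed genes moved when single libraries were left out. Each omission also made a group smaller, so a lost call need not mean a changed estimate. The count was 350 without normal replicate 2, 54 without normal replicate 3, 51 without siCCR1 replicate 1, 27 without siCCR1 replicate 2 and 113 without siCCR1 replicate 3. Of the 39 named genes that passed besides CCR1, 28 missed the threshold without siCCR1 replicate 2, 24 without normal replicate 3, 23 without siCCR1 replicate 1, 13 without siCCR1 replicate 3, 6 without normal replicate 1 and 1 without normal replicate 2.

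Phagocytosis, Fc and complement receptor genes had the smallest camera p of the 33 lists. Of 27 tested members, 9 fell, 0 rose and 18 did not pass over all genes tested, and 15 were lower adjusted over the list alone. The median log2 fold change was -0.37. CD14 (adjusted p = 9.39e-05 by edgeR), TREM2, FCGR3A and C1QC had the smallest p, and C1QA, the scavenger receptor CD36 (-0.57, adjusted p = 0.0176), FCER1G (-0.42), CR1 (-0.62) and FCGR2A (-0.37) also fell. FCER1G, CR1 and FCGR2A were named after their values were seen. FCGR3A has the near-identical neighbour FCGR3B, so its counts may be split between the copies. The list was lower as a set by camera (adjusted p = 2.69e-11), with adjusted p = 0.107 with an estimated correlation. Fry, which asks whether a list's genes move one way on balance, gave adjusted p = 0.00666. The list's median was also 0.187 higher in normal replicate 1 than in normal replicate 2, and it was -0.21 on FPKM without a filter.

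Genes of MHC class II presentation moved the other way. Of 14 tested members, 3 rose and 0 fell over all genes, and 8 were higher and 1 lower adjusted over the list alone, with a median of 0.24. HLA-DRA rose as given above, HLA-DQA1 rose from 0.866 ± 0.13 to 2.56 ± 0.307 CPM (log2 fold change 1.56, edgeR adjusted p = 0.0132) and HLA-DRB5 from 21.7 ± 0.845 to 29.3 ± 0.977 CPM (0.44, adjusted p = 0.0182). HLA-DRB5 is close in sequence to HLA-DRB1, and its reads may be shared. CD74, the invariant chain, gave 0.25 with adjusted p = 0.0781. The set was higher by camera (adjusted p = 6.09e-06), with adjusted p = 0.125 with an estimated correlation and 0.00535 by fry.

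**Figure D2:**
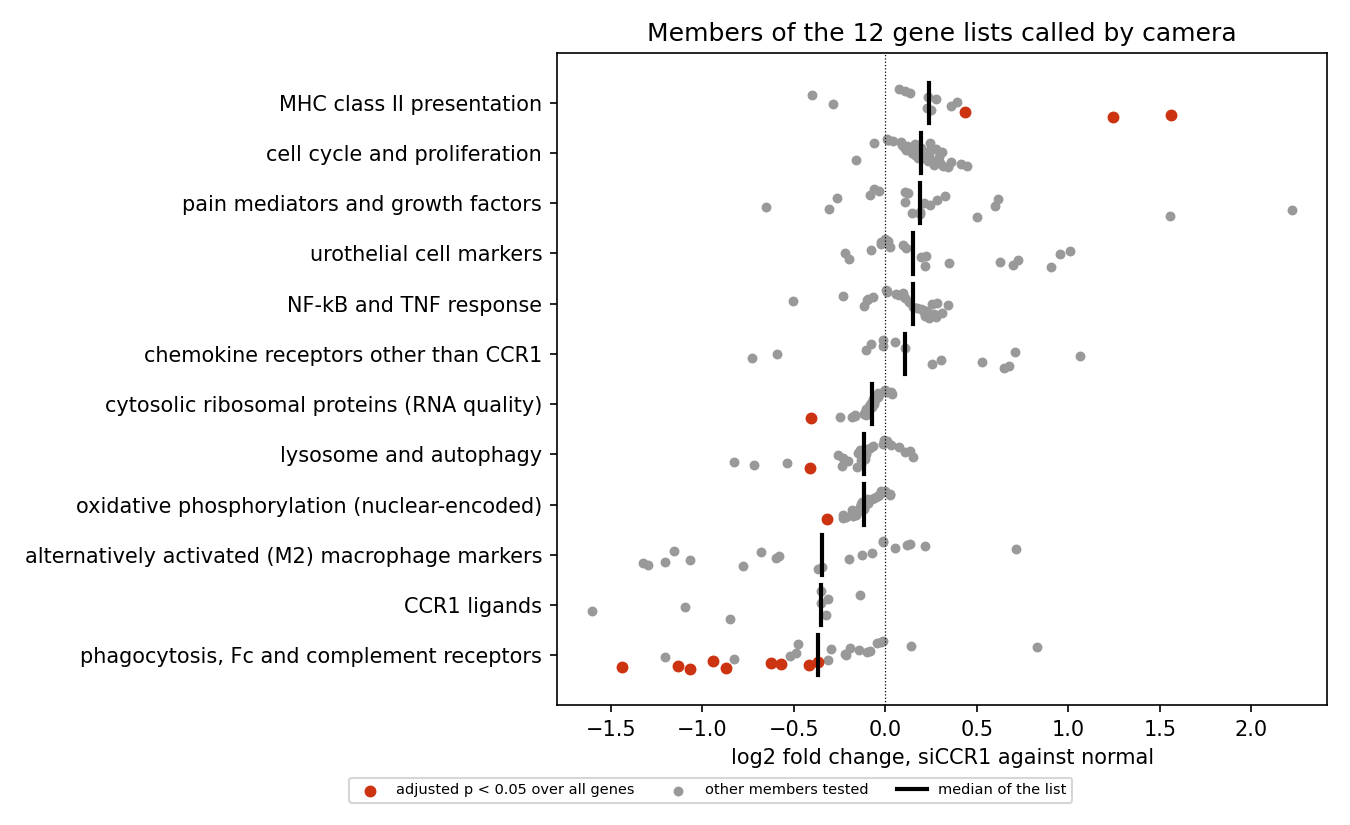
Log2 fold change, siCCR1 against normal, of each tested member of the 12 gene lists that camera called at a preset inter-gene correlation. With an estimated correlation camera called 0 of 33 lists. Red points passed adjusted p < 0.05 over all genes, grey points did not, and black lines mark list medians, from -0.37 for phagocytosis receptors to 0.24 for MHC class II.

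Markers of macrophage polarisation were compared because the study concerns a switch of phenotype. Among pro-inflammatory (M1) markers, 24 members were tested, of which IL23A rose (log2 fold change 0.88, edgeR adjusted p = 0.0132) and the Fc receptor FCGR1A fell (-0.48, adjusted p = 0.00384), while 22 did not pass. FCGR1A has near-identical copies that may share its reads. Adjusted over the list alone, 2 were higher and 2 lower. CCR7 gave 0.68 (adjusted p = 0.159) and TNF -0.40 (adjusted p = 0.162). IL1B gave -0.01 (0.999), IL6 -0.63 (0.433), CD86 -0.05 (0.88) and CD80 0.02 (0.98), each with its edgeR adjusted p in parentheses. IL6 passed without normal replicate 2 (-0.85, adjusted p = 0.0492) and was -0.36 without normal replicate 1. The M1 median was -0.0005 (camera adjusted p = 0.635), and it turned to 0.003 with upper-quartile factors. Without normal replicate 2 the M1 list was lower by camera (median -0.13, adjusted p = 0.00462), and without normal replicate 1 its median was 0.11 (adjusted p = 0.336).

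Among alternatively activated (M2) markers, 0 of 21 tested members passed in edgeR's test, 9 were lower at an unadjusted p under 0.05, and 6 were lower adjusted over the list alone. DESeq2 called 6 of them lower and limma-voom 0. The M2 median was -0.35, and the list was lower by camera (adjusted p = 0.00129), with adjusted p = 0.717 with an estimated correlation. Its median was also 0.285 higher in normal replicate 1 than in normal replicate 2. The median of the list was -0.04 on DESeq2 estimates and without a filter on low counts. It was -0.21 and -0.02 on FPKM with a pseudocount of 1, with and without the filter. Camera adjusted p was at most 0.0476 in these settings. The medians on DESeq2 estimates and without a filter also took in members too low for the main test, so they are not of the same genes as -0.35. Camera on DESeq2 estimates used only genes of the main fit. The haemoglobin scavenger receptor CD163 went from 80.1 ± 17.8 to 32 ± 7.48 CPM (-1.32, edgeR adjusted p = 0.117). PPARG (-0.37, adjusted p = 0.059), TGFB1 (-0.35, 0.0651), STAB1 (-0.78, 0.0764) and CLEC10A (-1.30, 0.109) had the smallest p. Without normal replicate 2, PPARG (-0.42, adjusted p = 0.0306), TGFB1 (-0.41, 0.0164) and STAB1 (-0.88, 0.047) passed. IL10 and MRC1 were too low to test, at 0 to 9 and 0 to 4 counts per library.

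The ligands of CCR1 all had negative estimates. Of 8 tested, 0 passed in edgeR's test, 3 were lower at an unadjusted p under 0.05, 3 were lower adjusted over the list alone, DESeq2 called 2 lower and limma-voom 0. CCL8 went from 321 ± 142 to 106 ± 21.4 CPM (-1.60, edgeR adjusted p = 0.249). CCL13 gave -0.85 (0.18), CCL7 -1.09 (0.553), CCL5 -0.32 (0.236) and CCL3 -0.35 (0.835), each with its edgeR adjusted p. Without normal replicate 1, CCL7 was -0.65 and CCL3 0.06, and CCL3 was -0.66 without normal replicate 2 and -0.17 without siCCR1 replicate 1. The ligand list was lower by camera (median -0.35, adjusted p = 0.0138), with adjusted p = 0.822 with an estimated correlation. The camera call was lost without normal replicate 1 (adjusted p = 0.236), normal replicate 3 (0.0532) or siCCR1 replicate 1 (0.109). The ligand median was -0.13 and -0.21 without normal replicate 1 and siCCR1 replicate 1, and -0.68 and -0.56 without normal replicate 2 and siCCR1 replicate 3. Other chemokine receptors had a median of 0.11, with 0 of 15 called by edgeR, 4 higher at an unadjusted p under 0.05, 2 higher adjusted over the list alone, 2 higher by DESeq2 and 0 by limma-voom. They were higher by camera (adjusted p = 0.0343), with adjusted p = 0.507 with an estimated correlation. That call was lost without normal replicate 1 (0.0921), siCCR1 replicate 1 (0.0813) or siCCR1 replicate 3 (0.0749), and on DESeq2 estimates (0.0663), with a minimum of 1 CPM (0.0965), with the replicate number as a block (0.0674) and on FPKM (0.0708 to 0.246). The receptor median was 0.26, 0.28 and 0.28 without normal replicates 1, 2 and 3, and 0.18 and 0.28 without siCCR1 replicates 1 and 2. It was 0.02 on FPKM without a filter and 0.18 without genes holding the 7-mers AGGCTTA or GGCTTAA, a setting chosen after seeing the data. ACKR3 (0.65, edgeR adjusted p = 0.0701) and CCR7 had the smallest p.

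Further lists were called by camera. The nuclear-encoded genes of oxidative phosphorylation had a median of -0.11, with 34 of 36 estimates negative. COX6A1 fell (-0.32, edgeR adjusted p = 0.0175), 4 were lower adjusted over the list alone, and the set had camera adjusted p = 7.24e-07, with adjusted p = 0.507 with an estimated correlation. Cytosolic ribosomal protein genes, listed as a sign of RNA quality, had a median of -0.07. Only RPLP0 of 40 was lower (-0.41, adjusted p = 0.0143), and 2 were lower adjusted over the list alone. Their camera adjusted p was 0.000221, with adjusted p = 0.828 with an estimated correlation, and 0.131 by camera without normal replicate 2. The call was also lost after a correction for GC content and gene length chosen after seeing the data (adjusted p = 0.113). The ribosomal median was -0.12 without normal replicate 1 and -0.03 without normal replicate 2. COX6A1 and RPLP0 each hold a part of 7 bases of the sequence AGGCTTAA named above. Such a part is also held by THBS1 and IL31RA, which rose. The whole sequence is held by CD4, which fell. Lysosome and autophagy genes had a median of -0.11, with 1 of 27 lower over all genes and over the list alone, the tetraspanin CD63 (-0.41, adjusted p = 0.0237). Their camera adjusted p was 0.00454, with adjusted p = 0.828 with an estimated correlation, and 0.296 by camera without normal replicate 1 (median -0.06).

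Cell cycle and proliferation genes had a median of 0.20, with 36 of 38 estimates positive. None passed over all genes (0 of 38 by edgeR), 19 were higher and 1 lower at an unadjusted p under 0.05, 3 were higher adjusted over the list alone, DESeq2 called 6 higher and limma-voom 0. The replication factor MCM3 gave 0.34 (edgeR adjusted p = 0.102) and TYMS 0.31 (0.131). The set had camera adjusted p = 9.93e-07, with adjusted p = 0.822 with an estimated correlation. Its median was 0.10 without siCCR1 replicate 3 and 0.13 without normal replicate 1. MKI67 and TOP2A of this list, which the naming rule did not pick, averaged 272 and 283 CPM in normal libraries. In siCCR1 libraries they averaged 308 and 313 CPM. How fully the THP-1 cells had matured into macrophages was not tested. NF-kB and TNF response genes had a median of 0.15, with 0 of 29 called by edgeR, 11 higher at an unadjusted p under 0.05, 4 higher adjusted over the list alone, 6 higher by DESeq2 and 0 by limma-voom. NFKB2 gave 0.24 (edgeR adjusted p = 0.0896) and TNFAIP3 0.28 (0.102), which passed without normal replicate 1 (0.34, adjusted p = 0.0479). The NF-kB set had camera adjusted p = 0.00252, with adjusted p = 0.828 with an estimated correlation, and 0.215 by camera without normal replicate 2 (median 0.09). Without normal replicate 1 the NF-kB median was 0.23.

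Pain mediators and growth factors had a median of 0.19. Of 21 tested, 0 passed by edgeR, by DESeq2 or over the list alone, and 6 were higher at an unadjusted p under 0.05. TGFA gave 0.50 (edgeR adjusted p = 0.175) and HBEGF 0.19 (0.336), or 0.11 (0.728) without siCCR1 replicate 2. Their camera adjusted p was 0.0343, with adjusted p = 0.822 with an estimated correlation. The call was lost without normal replicate 2 (0.299, median 0.05), siCCR1 replicate 2 (0.254) or siCCR1 replicate 3 (0.0554), without a filter on low counts (0.168), with a minimum of 1 CPM (0.373, median 0.11) and on FPKM (0.0963 to 0.143, median 0.04 without the filter). Urothelial cell markers, included because the medium came from urothelial cells, had a median of 0.15. Of 20 tested, 0 passed by edgeR, by DESeq2 or over the list alone, and 1 was higher at an unadjusted p under 0.05. KRT18, the most abundant of those named, was at 52.5 ± 5.87 CPM in normal and 61 ± 6.04 CPM in siCCR1 libraries (0.22, edgeR adjusted p = 0.389). Its log2 fold change was 0.12 (edgeR adjusted p = 0.632) without normal replicate 1. The urothelial list had camera adjusted p = 0.0343, with adjusted p = 0.828 with an estimated correlation. That call was lost without normal replicate 1 (0.501, median 0.05), siCCR1 replicate 1 (0.179) or siCCR1 replicate 2 (0.188), on DESeq2 estimates (0.077), with a minimum of 1 CPM (0.0987), with the replicate number as a block (0.0631), on FPKM with the filter (0.224 and 0.257) and without genes holding AGGCTTA or GGCTTAA (0.0629, with the median still 0.15), the last chosen after seeing the data. The urothelial median was 0.32 without normal replicate 3, 0.24 without siCCR1 replicate 3, and 0.09 and 0.05 on FPKM with a pseudocount of 1, with and without the filter. Limma-voom called 0 members of the pain and urothelial lists.

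Several lists without a camera call held single genes that changed. Monocyte and myeloid progenitor markers were listed to mark undifferentiated THP-1 cells, but their specificity to that state was not tested. Among them, the granule proteases PRTN3 (0.63, edgeR adjusted p = 0.00239) and ELANE (0.32, 0.0245) and the lysozyme gene LYZ (0.55, 0.00405) rose, and RNASE2 fell (-0.43, 0.015). Of these 19 markers, 3 were higher and 4 lower adjusted over the list alone (median -0.07, camera adjusted p = 0.752). Among 20 macrophage differentiation markers, CD14, CD36 and the colony-stimulating factor 1 receptor CSF1R (-0.43, 0.0288) fell, and 1 was higher and 3 lower adjusted over the list alone (median -0.08, camera adjusted p = 0.0964). CSF1R was also the only called gene of 23 in the JAK-STAT list (median -0.06, 0.446), where 2 were lower adjusted over the list alone. Single calls were BNIP3 (0.38) among 31 glycolysis and hypoxia genes (median 0.03, camera adjusted p = 0.0964), also the 1 call adjusted over the list alone, and IER5 (0.48) among 30 immediate early genes (-0.02, 0.783), with 1 higher and 4 lower adjusted over the list alone in the latter. THBS1 was the call among 27 matrix and adhesion genes (0.02, 0.821), with 4 higher and 4 lower adjusted over the list alone.

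Single falls were CDKN1A (-0.46) among 27 p53 and apoptosis genes (median 0.01, mean -0.02, camera adjusted p = 0.949), TLR8 (-0.37) among 24 double-stranded RNA and toll-like receptor genes (median 0.002, mean -0.07, 0.375), CD4 (-0.37) among 15 lymphocyte markers (-0.06, 0.112) and SLC30A1 (-0.30) among 21 oxidative stress and metal response genes (-0.01, 0.237). Adjusted over the list alone, 1 gene was lower in each of these lists but the last, which had 1 higher and 2 lower. Monocytes also express CD4. Type I interferon response genes had 0 of 37 members called by edgeR or over the list alone, 1 higher and 4 lower at an unadjusted p under 0.05 and 2 lower by DESeq2 (median -0.08, camera adjusted p = 0.0973). Inflammasome genes had 0 of 18 called by edgeR and by DESeq2 (2 higher and 3 lower unadjusted, median -0.02, 0.637), and other chemokines 0 of 15 by edgeR and 1 lower by DESeq2 (1 higher and 1 lower unadjusted, 1 lower adjusted over the list alone, median 0.02, 0.357). Cholesterol efflux and lipid genes had 0 of 19 called, with 3 higher and 1 lower adjusted over the list alone and 2 higher and 1 lower by DESeq2 (4 higher and 3 lower unadjusted, median 0.01, 0.832). Sterol synthesis had 0 of 25 called by edgeR and 1 higher by DESeq2 (2 higher and 1 lower unadjusted, median 0.03, 0.357). Adjusted over the list alone, the inflammasome and sterol lists had 0 calls, and limma-voom called 0 in each of the 5 lists from interferon to sterol synthesis.

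The unfolded protein and integrated stress response list had 0 of 29 called by edgeR and by DESeq2 (2 higher and 2 lower at an unadjusted p under 0.05, median 0.08, camera adjusted p = 0.121). The RNA interference machinery had 0 of 13 called by edgeR and by DESeq2, and 1 higher and 1 lower adjusted over the list alone (2 higher and 1 lower unadjusted, median 0.04, 0.637). Fibroblast and endothelial markers had 0 of 13 called by edgeR and 1 lower by DESeq2 (1 higher and 2 lower unadjusted, 2 lower adjusted over the list alone, median -0.16, mean 0.01, 0.341). Mitochondrially encoded genes (0 of 15 called by edgeR and by DESeq2, 2 higher unadjusted, median 0.02, 0.433) and replication-dependent histones (0 of 7 called, 0 unadjusted, median -0.01, 0.752), which track RNA quality and RNA without a poly(A) tail, gave no call in either direction. The stress response, mitochondrial and histone lists also had 0 calls adjusted over the list alone, and limma-voom called 0 members in each of these 5 lists. The cytosolic ribosomal protein list, also set as a sign of RNA quality, was called lower by camera as given above (adjusted p = 0.000221). By camera with an estimated correlation, 0 of 33 lists passed and 2, the phagocytosis and MHC class II lists, had an unadjusted p under 0.05, while fry called those 2.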

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

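Alternatives were fixed before the data were examined, except the GC content and gene length correction and the removal of genes with the 7-mers, which were chosen only after the result was seen. The fall of CCR1 passed in each of its 17 alternatives, from -1.34 to -1.50, with adjusted p of at most 0.0392. CD14, CREG1, HLA-DRA and SLC11A1 were the 4 of 39 other named, called genes that passed in all 17. The count of changed genes (215) stayed within 1.5 times with other scaling factors (212 and 215), limma-voom (181), other count filters (275 and 300) and the GC and length correction (206, of which 84 higher and 122 lower). Taking genes that hold the 7-mers out of the 215 left 167. No new fit or adjustment was made there, so that count does not check the calls. DESeq2 called 675 genes (343 higher, 332 lower, 51 at least 2-fold), of which 210 were among the 215. Limma on FPKM called 106 with a pseudocount of 1 (49 higher, 57 lower, 7 at least 2-fold), 87 with 0.1 (40, 47 and 10) and 6 without a filter (2, 4 and 4). Leaving out each library in turn gave 27 to 350 genes (13 to 121 higher, 14 to 229 lower, 8 to 48 at least 2-fold), and 8 to 12 lists. With the replicate number as a block, 44 genes were called (22 higher, 22 lower, 8 at least 2-fold), all of them among the 215, and 10 lists. The numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.082, 0.023 and 0.16, and only replicate 3 matched its own number best. The 12 lists called by camera became 0 with an estimated correlation and 2 with fry. The 12 and the 0 lists came from the same fit and differed in camera's correlation setting. That setting also changes the degrees of freedom of camera's test, so the loss cannot be credited to correlated genes alone. Why the count of changed genes moved between settings was not tested. Estimates near 0 changed sign without a call. IL1B was 0.00 with DESeq2, 0.06 with limma-voom, 0.06 with the block, 0.08, 0.09 and 0.08 on FPKM and 0.02 after the GC and length correction, against -0.01. CCR2 was 0.01, 0.02 and 0.01 on FPKM against -0.02. Without single libraries, IL1B ran from -0.28 to 0.29, CCR2 from -0.09 to 0.09, CCL3 from -0.66 to 0.06, CD86 from -0.11 to 0.03, CD80 from -0.13 to 0.15 and the M1 median from -0.13 to 0.11. Some genes were too low to be tested at all: IL10 had 0 to 9 counts per library and MRC1 0 to 4. Total counts were at least 50935979 per library, and whether depth was the reason was not tested.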

Other observations

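The tests of undifferentiated cells and of a swap between the groups, the GC and length correction, the classes of sites built on the leading 7-mers, and all values on zinc finger and haemoglobin genes were chosen only after the result was seen. Most zinc finger genes had positive estimates in siCCR1 against normal libraries. Of 483 tested genes with a ZNF symbol, 349 had a positive estimate, 8 rose and 0 fell in edgeR's test, and 345 to 353 were positive with other scaling factors and tools. The cluster on chromosome 19 between 19668796 and 24129961 (GENCODE release 29, GRCh38) was singled out after its values were seen, so no test is given for it. There, 32 of 34 tested ZNF genes were positive with a median log2 fold change of 0.43, and 0.42 after the GC and length correction. ZNF93 (0.47, edgeR adjusted p = 0.00405), ZNF85 (0.46, 0.0213), ZNF429 (0.47, 0.041) and ZNF737 (0.69, 0.0433) passed. The mean log2 CPM of the 34 genes was 2.33, 2.42 and 2.48 in normal libraries and 2.79, 2.83 and 2.84 in siCCR1 libraries. The other 23 tested genes of that region had a median of 0.29, with 18 positive. Members of this family are similar in sequence, and reads shared among them were not ruled out.

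Haemoglobin transcripts (HBA1, HBA2, HBB and HBD) took 1.53 to 2.25% of the counts in each library of this monocytic line. HBB (edgeR adjusted p = 0.93) was at 5573 ± 1080 CPM in normal and 5363 ± 507 CPM in siCCR1 libraries (SD, n = 3), while HBA2 and HBA1, whose coding sequences are identical, so that reads can be shared, had normal means of 6932 and 5508 CPM. ALAS2, the erythroid haem synthesis enzyme, was at 11.8 ± 2.77 and 11.1 ± 1.46 CPM. CAP1, PPT1 and SMAP2, neighbours on chromosome 1, were among the abundant genes, with normal means of 7611, 5077 and 3606 CPM.

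Genes that fell in siCCR1 libraries may in part be off-targets of the siRNA, whose sequence is not given in the sources used here, so a consequence of losing CCR1 stays open for holders of the words below and for the other genes alike. Of 16349 words of 7 bases in 3' untranslated regions, AGGCTTA went with the largest fall (z = -8.76, family-wise permutation p = 0.001, the smallest that 1000 permutations can give), and it occurs in the CCR1 coding sequence in exon 2 (chromosome 3, 46203807 to 46203813), as 14.3% of the words do in the CCR1 transcript. GGCTTAA (p = 0.001), TGGCTTA (0.015) and TAGGCTT (0.041) also passed by family-wise permutation, and none of these is in the CCR1 transcript. Each shares most of its bases with AGGCTTA, so they are not independent of it. Their absence from CCR1 does not count against a route through AGGCTTA. AGGCTTA or the overlapping GGCTTAA was held by 34.3% of the 108 fallen genes searched, against 14.5% of all genes and 12% of the 92 that rose, and 3.19% of genes with the joint 8-mer AGGCTTAA fell against 0.603% of those without a site, although the median of the 8-mer genes was only -0.03 and 0 of 124 genes with both 7-mers apart fell. GC content or gene length as the whole cause is argued against, since 98.1% of the median fall was kept after the correction. An innate response to transfected RNA stays open. The interferon list did not rise as a set (median -0.0789), which the rule set before the test counted against such a response. A condition on the spread between libraries was added to that rule. The upper bound, the median plus a t multiple of the SE between libraries (0.132), was 0.288. The list's mean ranged by 0.454 among normal and by 0.041 among siCCR1 libraries.

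The fall of Fc, complement and scavenger receptor genes was weighed against the same off-target route. Among the 9 members that fell, 2 held either 7-mer (CD36 and CR1). Without the holders in the list the median was -0.34 and camera gave adjusted p = 4.41e-10. That p assumes a preset correlation, and over the alternatives of this list it ran from 2.25e-31 to 0.107. The median kept without the holders argues against direct silencing through these 7-mers as the whole cause. Falls that follow from other silenced genes were not tested, so an indirect off-target effect stays open. A larger share of undifferentiated cells stays open. Of the markers listed for that state, whose specificity was not tested, PRTN3, LYZ and ELANE rose and RNASE2 fell. The 19 tested went both ways (median -0.0724, camera adjusted p = 0.752). A response to transfection and an effect of CCR1 loss stay open too and could not be separated, since no library with a control siRNA is labelled as such.

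The normal libraries differed among themselves at inflammatory genes. All 24 tested M1 markers were higher in normal replicate 1 than in normal replicate 2, with a median log2 difference of 0.63, at the 100th percentile of 10000 random lists of the same size matched on mean expression, and CCR1 ligands differed by 1.4. The M2 list (0.285, percentile 99.96) and the phagocytosis list (0.187, percentile 99.9) also differed between these libraries. So did the NF-kB and TNF response (0.267), type I interferon (0.351) and other chemokine (0.896) lists, each at percentile 100. MHC class II did not stand apart (-0.00588, percentile 51.65). Genes of a fixed list may vary together and random genes need not, so the percentiles do not measure how unusual these shifts were. This pair was also the furthest apart of the normal libraries (chi-square per degree of freedom of 40.1, against 16.4 and 20.9). Normal replicate 3 lay between them, with M1 means of 5.615, 4.886 and 5.287 log2 CPM in normal replicates 1, 2 and 3. GC content or gene length is argued against, as 98.8% of the M1 difference was kept after the correction, and a swap between the groups is argued against by CCR1, which in the lowest normal library lay 117 CPM above the highest siCCR1 library. A difference between cultures or in exposure to the medium may lie behind it, and no biological explanation was tested.

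The grouping itself was checked with the 10 splits of the 6 libraries into 3 and 3, too few for a share under 0.05. The real split gave 215 genes and the highest other split 4, and 1 split, the real one, reached 215. Every other split mixed normal and siCCR1 libraries, so a real difference would widen the spread within its groups. The 4 genes are therefore not a count expected by chance. For lists the real split gave 12 and the highest other 17, and 4 splits reached 12 or more.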
